A study of Arabidopsis thaliana with 8 samples.

How the data were processed

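Total RNA of Arabidopsis thaliana, accession Col-0, was measured on 8 one-colour microarrays, 4 of roots and 4 of flower buds. Per the labels, plants were raised in hydroponics until 6 weeks of age, and each biological replicate was tissue pooled from 8 to 10 plants. RNA was extracted with a phenol reagent and spin columns and labelled with the dye Cy3 by linear amplification, per the labels' protocols.

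For each array the deposited scanner file gave spot intensity on a linear scale, with 62976 features, of which 61657 were spots of 43603 probes that are not controls. Per the file headers, Agilent Feature Extraction 10.10.1.1 had subtracted the background within each array and raised dim spots to a small positive floor, and no scaling between arrays had been applied to this intensity. Flags of the same software, per the file headers, marked spots well above background, saturated spots and outlier spots. After the last feature, 6 of the files repeated earlier lines and ended in the middle of a line. The 408 repeated lines were identical to their first copies and were dropped. The deposited value table held log2 values whose making is not given in the sources used here. Set against the scanner files, its columns followed the log2 signal shifted to each array's 75th percentile and then centred on the probe's median over the 8 arrays, with correlations of at least 0.9993 per array. Scale, centring and direction were thereby settled from the values. The medians of its columns were -0.0098, 0.0957, 0.0908 and 0.0263 for root replicates 1 to 4 and -0.0084, -0.0559, -0.0417 and -0.0592 for flower bud replicates 1 to 4.

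Control spots and the 6 to 191 outlier spots of each array were left out, and no spot was saturated. The log2 of the processed signal was averaged over the spots of a probe, and the 75th percentile of each array was subtracted. Probes were matched to genes through the transcript accessions of the design and the RefSeq gene table of the organism, used for names and for gene order alone. Of the 43603 probes, 34285 matched 1 locus and 9318 matched none and were not named. The 25383 loci with a probe were each represented by the probe with the highest mean over the 8 arrays, and 6919 of them had more than 1 probe. Among 6512 genes with more than 1 tested probe, 23 had probes called in opposite directions and 640 had some probes called and some not; none of the 23 is named below.

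A gene was tested if its probe was well above background on all 4 arrays of at least 1 tissue, which left 22263 genes. Differences are flower bud minus root on the log2 scale, fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3 with tissue as the single factor, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05 and a fitted difference of 2-fold or more. Where the probe was not well above background on any array of a tissue, the difference is given as a bound: the mean of the brighter tissue over 4 arrays against the mean, in the dimmer tissue, of the higher of the probe's own signal and the lowest signal well above background on that array. This limit is lenient, since a probe can exceed that lowest signal without being well above background. Before the fold of a single gene, the words "at least" refer to this bound alone. Where a probe was well above background on only some arrays of a tissue, the fitted difference is given. It rests in part on signal not well above background. Standard errors are those of the limma fit. The number of arrays limits the precision, and because the replicates are pools of plants, p-values measure the spread between these pools and not between single plants. All 8 arrays lay on 1 slide and were scanned on 1 date. Roots lay in its first row and buds in the second, so that row and tissue cannot be told apart, and the column on the slide followed the replicate number.

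Before the data were examined, 26 gene lists with 438 members were fixed, along with the rule for naming genes, the design of each test and the alternatives. Of the members, 431 were used. The gene A6 was left out because the reference table gives its locus another name, and PRD1, PRD3, FAR4, FRD3, TCH3 and ACT2 had no matched probe. Lists were tested with camera at a preset correlation of 0.01, with camera at a correlation estimated from the arrays, and with fry, which asks whether the members of a list move one way without setting them against other genes. The named genes are the 5 called genes with the largest difference in each direction among those well above background on all 8 arrays, and the 5 with the largest bound in each direction. From each list they are the 2 called members with the largest difference in the prevailing direction and the largest in the other. In lists with fewer than 2 called members, the 2 members with the largest difference were to be named. All reproductive actins and reference genes are named. The result of 1 gene that this rule selects is not reported here. Where 5 or fewer members of a list missed the thresholds, they are named too, which was chosen after their values were seen.

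The fit and the list test were tested on simulated arrays of the 22263 genes with 200 changed genes. For the comparison of flower buds with roots, 76 of 100 genes changed by 1.5 on the log2 scale and 95 of 100 changed by 3 were called, with 12 unchanged genes called. Genes were drawn independently of each other there, without array floors or differences in scaling. Only 200 genes were changed there, whereas 54.9% of the tested genes were called in the data, and the adjusted p depends on that share. These rates therefore do not carry over to the data, to correlated genes or to lists whose members are correlated. The alternatives were background correction by normexp on the median spot signal with an offset of 50, quantile normalization, centring on the array median, scaling on the reference genes, other filters on dim probes, other ways of treating several probes of a gene, the deposited value table, other settings of eBayes, array weights, other thresholds, the replicate number as a block and leaving out each array in turn. Omitting root replicates 2 and 3 together and raising every value to the highest floor of the 8 arrays were added after seeing the data. Scaling on spike-in probes was not run because the median processed signals over all their spots, 4.76 to 15.1 per array, lay near background. The brightest of these probes was well above background on 35 of 35 spots on each flower bud array and on root replicates 1 and 4. On root replicates 2 and 3 it was so on 4 and 1 of 35 spots. A slide block was not run because there was 1 slide. Files were read and summarised with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.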

Results

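Transcript signals of roots and flower buds were compared in 6-week-old plants of Arabidopsis thaliana, with 4 arrays per tissue and tissue of 8 to 10 plants behind each array. The 75th percentile of the processed signal was 3073, 2218, 3153 and 2702 on root replicates 1 to 4 and 4184, 4149, 4164 and 4258 on flower bud replicates 1 to 4. Differences are given as log2 of flower bud minus root ± SE with n = 4 arrays per tissue, and a positive value is higher in flower buds.

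Flower buds carried much higher transcript levels of a plastid aldolase gene and a Rubisco subunit gene, and roots carried much higher levels of a water channel gene and of a nitrate transporter gene. Among genes measured in both tissues, the largest differences towards flower buds were those of BGLU18 (AT1G52400), a beta-glucosidase, at 10.90 ± 0.17, of FBA2 (AT4G38970), a plastid aldolase, at 10.86 ± 0.21, and of RBCS2B (AT5G38420), a small subunit of Rubisco, at 10.57 ± 0.17. The loci AT4G29030 and AT2G10940 followed at 10.43 ± 0.18 and 10.42 ± 0.30. The largest differences towards roots were -13.97 ± 0.17 for MLP329 (AT2G01530), a major latex protein-like gene, -13.24 ± 0.16 for AT5G64100 and -12.66 ± 0.12 for TIP2;3 (AT5G47450), a water channel of the vacuolar membrane. AT5G48430 and AT5G26280 were also higher in roots, at -12.59 ± 0.20 and -12.41 ± 0.23. In limma with Benjamini-Hochberg adjustment, these 10 genes had adjusted p-values of at most 1.43e-08.

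Other genes were well above background in 1 tissue alone. GRP19 (AT5G07550), which encodes a glycine-rich oleosin of the pollen coat, was at least 7887-fold higher in flower buds. AT1G66850, AT1G11850, AT5G33370 and E13L3 were at least 6703-fold, 3805-fold, 2800-fold and 2413-fold higher there. In the other direction, AT3G01190 was at least 46063-fold higher in roots, and AT4G39675, AT1G05240, AT3G05950 and AT4G15390 were at least 30056-fold, 15714-fold, 15212-fold and 13293-fold higher. For AT4G39675 the bound equals the fitted difference and so rests on flower bud signal that was not well above background.

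Of 22263 genes tested with limma, 12220 were called, or 54.9%, of which 6708 were higher in flower buds and 5512 higher in roots. The fitted difference was 16-fold or more for 1950 genes higher in flower buds and for 1824 higher in roots. These counts include genes not well above background in 1 tissue. For 1609 of the calls higher in flower buds and 646 higher in roots, the probe was not well above background on any array of the other tissue. These calls were made on the fitted difference and not on the bound, so they rest in part on signal not well above background. The larger number of calls towards flower buds depended on the processing. Their share of the calls was 54.9% as reported and 63.3% with scaling on the reference genes, but 50.5% with centring on the array median. It turned to a minority under normexp (49.7%), without a filter on dim probes (49.5%) and among genes well above background on all 8 arrays (47.4%). Across genes, which are not independent replicates, Pearson's r between arrays was 0.971 to 0.993 within a tissue and 0.483 to 0.532 between tissues.

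**Figure D1:**
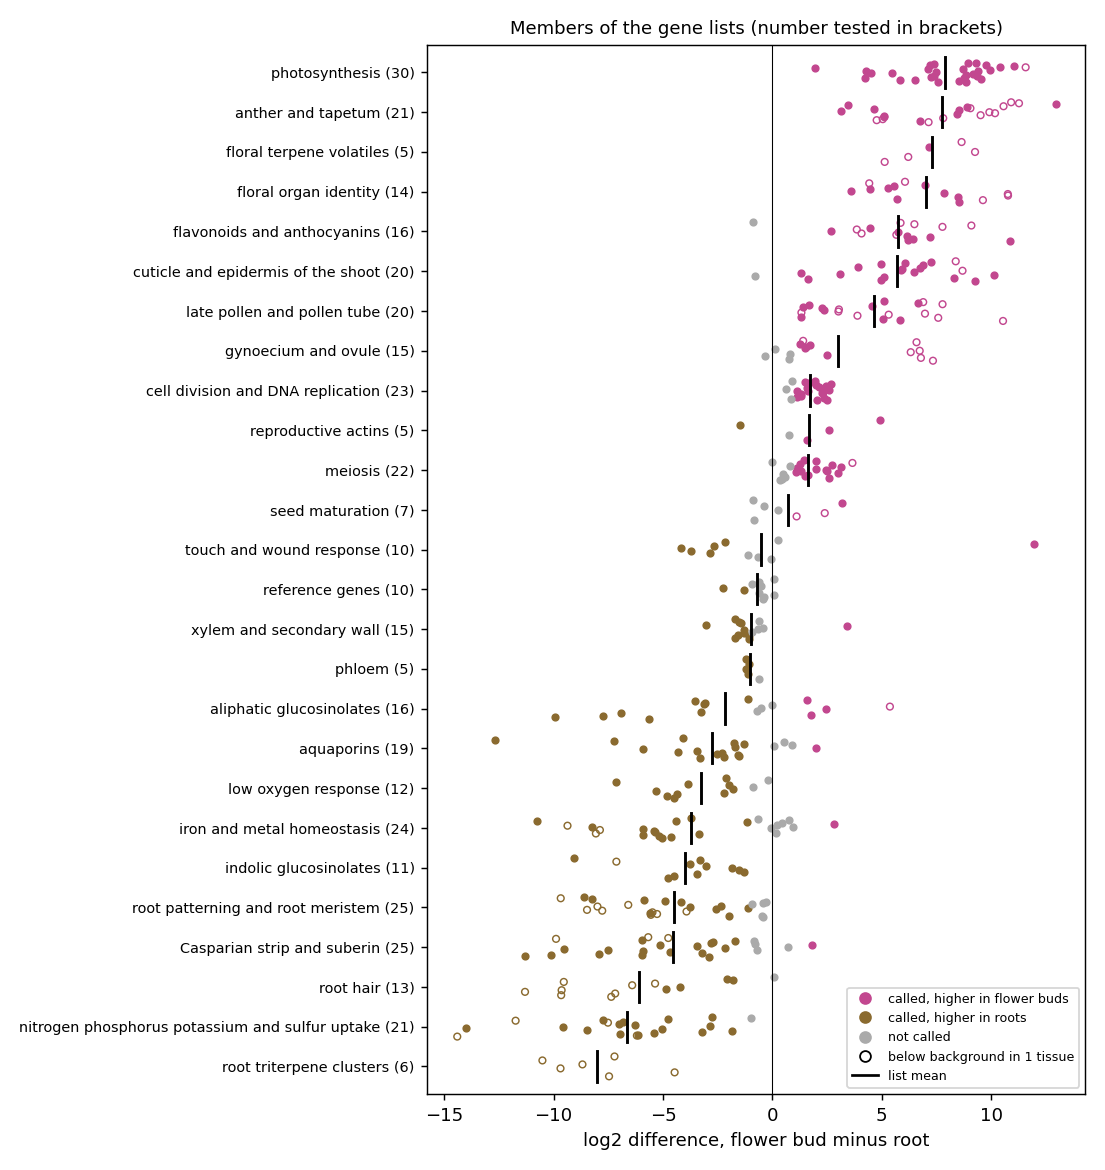
Log2 difference between flower buds and roots for each tested member of the 26 gene lists, with lists ordered by their mean (black bars) and the number of tested members in brackets. Points are coloured by the tissue with the higher signal where called and grey where not called, and open points mark members below background on all arrays of 1 tissue; means run from -8.00 for the root triterpene list to 7.88 for the photosynthesis list and use fitted values for the open points.

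Gene lists were set against all other genes with camera, and for all 26 lists the counts adjusted over the list alone were the same as those over all genes tested. With a preset correlation 22 lists passed. With an estimated correlation 0 of the 26 passed after adjustment, and the estimated-correlation value is given with each list. List means and the camera tests use the fitted values of all tested members, including those below background in 1 tissue. Normexp background correction moved the difference of 57 of the 88 named genes and the mean of 16 of the 26 lists by over 1.5-fold. Keeping only genes well above background on all 8 arrays moved the mean of 13 of 23 lists by over 1.5-fold, for example from -6.10 to -2.58 for root hair, from 3.01 to 1.14 for gynoecium and ovule, from 7.77 to 4.94 for anther and tapetum and from -4.52 to -2.72 for Casparian strip and suberin genes.

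Floral organ identity genes, the transcription factors that specify sepals, petals, stamens and carpels, were higher in flower buds in 14 of 14 cases. SEP1 and SEP2, both MADS-box genes, were at least 859-fold and 778-fold higher. The list had a median difference of 6.52 (camera adjusted p = 1.50e-05, adjusted p = 0.0907 with an estimated correlation). Of 15 gynoecium and ovule genes 11 were higher in flower buds, led by the YABBY genes CRC and INO at least 89.1-fold and 53.5-fold higher (camera adjusted p = 0.00255, adjusted p = 0.188 with an estimated correlation). SPT, BEL1, HEC1 and NGA3 were not called, with differences of 0.77, -0.33, 0.82 and 0.13.

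All 21 anther and tapetum genes tested were higher in flower buds, with a mean difference of 7.77 (camera adjusted p = 2.47e-07, adjusted p = 0.120 with an estimated correlation). GRP17, a pollen coat oleosin, differed by 12.94 ± 0.58 and was well above background on 1 of 4 root arrays, while the pollen coat lipase EXL4 was at least 1409-fold higher. The 20 late pollen and pollen tube genes tested were likewise all higher in flower buds (camera adjusted p = 7.96e-05, adjusted p = 0.261 with an estimated correlation). VGD1, a pectin methylesterase of pollen tubes, was at least 877-fold higher and the proton pump AHA9 at least 180-fold higher. This list also differed between the flower bud arrays themselves, with median deviations from the tissue mean of 0.90, 0.27, -0.19 and -0.86 on replicates 1 to 4.

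Meiosis genes were called in smaller differences: 16 of 22 were higher in flower buds and 6 were not called (mean 1.64, camera adjusted p = 0.000673, adjusted p = 0.188 with an estimated correlation). The crossover gene SHOC1 was at least 6.25-fold higher and the A-type cyclin TAM differed by 3.12 ± 0.13; under normexp the difference of SHOC1 was 0.89 and was not called. Genes of cell division and DNA replication were higher in flower buds for 20 of 23 members (mean 1.74, camera adjusted p = 1.60e-05, adjusted p = 0.261 with an estimated correlation). MCM6, a subunit of the replicative helicase, differed by 2.68 ± 0.23 and the kinesin HINKEL by 2.57 ± 0.16. The members CYCB1;3, MAD2 and CDC45 were not called, at 0.87, 0.63 and 0.89.

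Photosynthesis genes were higher in flower buds for 30 of 30 members (mean 7.88, camera adjusted p = 7.75e-12, adjusted p = 0.0842 with an estimated correlation). The Calvin cycle gene SBPASE was at least 2039-fold higher. GAPB, a plastid glyceraldehyde-3-phosphate dehydrogenase, differed by 11.04 ± 0.19 and was well above background on 2 of 4 root arrays. Of the 30 genes, 25 were well above background on all 8 arrays, where the median root signal was 0.52% of the flower bud signal.

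Shoot cuticle and epidermis genes were higher in flower buds for 19 of 20 members (mean 5.71, camera adjusted p = 3.66e-07, adjusted p = 0.0842 with an estimated correlation). CYP77A6, a cutin hydroxylase, differed by 10.14 ± 0.67 and CER1, which acts in wax alkane synthesis, by 9.27 ± 0.16. CYP77A6 was well above background on 1 of 4 root arrays, and its difference was 10.85 without root replicate 2. The cutin gene CYP86A2 was not called, at -0.78.

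Flavonoid and anthocyanin genes were higher in flower buds for 15 of 16 members (mean 5.73, camera adjusted p = 9.08e-05, adjusted p = 0.120 with an estimated correlation). Chalcone synthase, CHS, differed by 10.87 ± 0.43 and was well above background on 1 of 4 root arrays. MYB21, a transcription factor of petals and stamens, was at least 306-fold higher in flower buds, and the methyltransferase gene OMT1 was not called, at -0.90. All 5 floral terpene genes were higher in flower buds (mean 7.29, camera adjusted p = 0.0225, adjusted p = 0.342 with an estimated correlation). The terpene synthase genes TPS14 and TPS11 were at least 276-fold and 193-fold higher, and with scaling on the reference genes the camera adjusted p of the list was 0.0502. The median deviations of this list were 1.02, 0.61, 0.20 and -1.51 on flower bud replicates 1 to 4. Its mean was 7.91 without flower bud replicate 4 and 4.40 under normexp.

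Root patterning and root meristem genes were higher in roots for 20 of 25 members (mean -4.50, camera adjusted p = 8.20e-08, adjusted p = 0.0907 with an estimated correlation). AGL17, a MADS-box gene, was at least 703-fold higher in roots, and AGL21 of the same family differed by -8.59 ± 0.24 and was well above background on 1 of 4 flower bud arrays. SHR, SCR, ARF7, ARF19 and IAA14 were not called, at -0.43, -0.48, -0.95, -0.42 and -0.30. Root hair genes were higher in roots for 12 of 13 members (mean -6.10, camera adjusted p = 1.78e-05, adjusted p = 0.120 with an estimated correlation). The expansin EXPA7 was at least 1440-fold higher and the transcription factor RSL2 at least 740-fold higher, whereas SCN1 was not called, at 0.08.

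Casparian strip and suberin genes, which build the diffusion barrier of the endodermis, were higher in roots for 20 of 25 members (mean -4.52, camera adjusted p = 3.90e-06, adjusted p = 0.120 with an estimated correlation). The scaffold gene CASP1 differed by -11.28 ± 0.19 and was well above background on 3 of 4 flower bud arrays. KCS2, an elongase of very long chain fatty acids, was higher in flower buds by 1.83 ± 0.11. GPAT5, FAR1, KCS20 and MYB53 were not called, at -0.69, 0.73, -0.78 and -0.84.

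Uptake genes for nitrogen, phosphorus, potassium and sulfur were higher in roots for 20 of 21 members (mean -6.65, camera adjusted p = 2.41e-09, adjusted p = 0.0907 with an estimated correlation). NRT2.1, a high-affinity nitrate transporter, was at least 10042-fold higher in roots, and the phosphate transporter PHT1;1 differed by -14.02 ± 0.14 and was well above background on 3 of 4 flower bud arrays. BOR1, a boron transporter, was not called, at -0.97. Iron and metal genes were higher in roots for 16 of 24 members, with 1 higher in flower buds and 7 not called (mean -3.74, camera adjusted p = 0.000356, adjusted p = 0.157 with an estimated correlation). FPN2, a vacuolar metal transporter, differed by -10.76 ± 0.31 and was well above background on 1 of 4 flower bud arrays, and the nicotianamine synthase NAS2 was at least 352-fold higher in roots. OPT3, an oligopeptide-family transporter, was higher in flower buds by 2.80 ± 0.21.

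Aquaporin genes were higher in roots for 15 of 19 members (mean -2.75, camera adjusted p = 0.000350, adjusted p = 0.261 with an estimated correlation). Next to TIP2;3 at -12.66 ± 0.12, TIP2;2 differed by -7.22 ± 0.21, while PIP2;5 of the plasma membrane was higher in flower buds by 2.00 ± 0.19. PIP2;7, PIP2;8 and TIP2;1 were not called, at 0.07, 0.91 and 0.55.

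The glucosinolate lists, which hold genes of sulfur-rich defence compounds, differed from each other in their counts. Of the indolic genes 11 of 11 were higher in roots (mean -3.98, camera adjusted p = 6.99e-05, adjusted p = 0.120 with an estimated correlation), with the cytochrome P450 CYP81F4 at -9.07 ± 0.26 and the regulator MYB122 at least 104-fold higher in roots. Of the 16 aliphatic genes 9 were higher in roots, 4 higher in flower buds and 3 not called, and the list did not pass (mean -2.15, camera adjusted p = 0.0613, adjusted p = 0.588 with an estimated correlation). The chain elongation genes MAM3 and BCAT4 differed by -9.92 ± 0.62 and -7.76 ± 0.57, and MYB29, a regulator of the aliphatic pathway, was at least 18.7-fold higher in flower buds. MAM3 was well above background on 3 of 4 flower bud arrays and its difference was -9.32 without flower bud replicate 4. FMOGS-OX1, MYB28 and UGT74C1 were not called, at -0.72, -0.51 and -0.01. Camera adjusted p-values for the aliphatic list were 0.0368 without flower bud replicate 1, 0.0424 without flower bud replicate 2 and 0.0283 with scaling on the reference genes. Its median deviations from the tissue mean were 0.57, 0.32, -0.18 and -0.77 on flower bud replicates 1 to 4.

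Genes of the root triterpene clusters were higher in roots for 6 of 6 members, all as bounds (median with bounds -7.18, camera adjusted p = 0.000795, adjusted p = 0.0964 with an estimated correlation). PEN1, an oxidosqualene cyclase, was at least 835-fold higher and the thalianol pathway desaturase THAD at least 446-fold higher.

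Xylem and secondary wall genes were higher in roots for 10 of 15 members (median -1.30, camera adjusted p = 0.000795, adjusted p = 0.261 with an estimated correlation). The xylem protease XCP1 differed by -3.03 ± 0.15 and FLA12, a fasciclin-like arabinogalactan protein, by -1.70 ± 0.21, while LAC17, MYB46, MYB83 and FLA11 were not called, at -0.93, -0.64, -0.44 and -0.59. The wall regulator NST1 was higher in flower buds by 3.40, with an SE of 1.1, and was well above background on 1 of 4 root arrays. Its difference was 2.64 without root replicate 1, 4.60 without root replicate 3 and 1.00, not called, under normexp. Phloem genes were higher in roots for 4 of 5 members (mean -1.04, camera adjusted p = 0.0225, adjusted p = 0.175 with an estimated correlation). PP2-A1, a phloem lectin, differed by -1.19 ± 0.15 and SEOR1, a sieve element filament protein, by -1.18 ± 0.10, and both were under 2-fold with scaling on the reference genes, at -0.88 and -0.87. The sucrose carrier SUC2 was not called, at -0.61.

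Low oxygen response genes were higher in roots for 10 of 12 members (mean -3.26, camera adjusted p = 0.00189, adjusted p = 0.261 with an estimated correlation). The transcription factor HRE1 differed by -7.13 ± 0.15 and the sucrose synthase SUS4 by -5.32 ± 0.42, and HRA1 and AlaAT1 were not called, at -0.90 and -0.20. The median deviations of this list from the tissue mean were 0.72, 0.06, 0.43 and -1.12 on root replicates 1 to 4. Of 10 touch and wound response genes 5 were higher in roots, 1 was higher in flower buds and 4 were not called, and the list did not pass (mean -0.52, camera adjusted p = 0.180, adjusted p = 0.588 with an estimated correlation). The zinc finger genes ZAT10 and ZAT12 differed by -4.18 ± 0.51 and -3.74 ± 0.49, against 11.96 ± 0.56 for the plastid lipoxygenase LOX2, which was well above background on 1 of 4 root arrays. TCH2, TCH4, WRKY40 and OPR3 were not called, at -0.06, -0.67, -1.13 and 0.26. The median deviations of this list were -0.64, -0.53, 0.30 and 0.83 on root replicates 1 to 4. On flower bud replicates 1 to 4 they were 0.49, 0.13, -0.16 and -0.30.

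**Figure D2:**
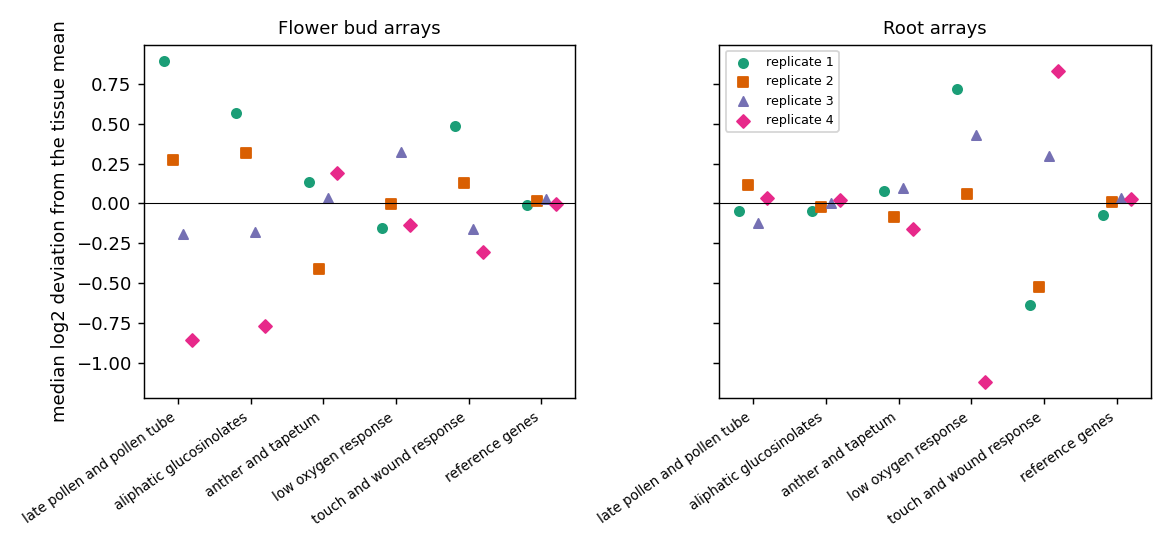
Median log2 deviation of 6 gene lists from the mean of their tissue, on each of the 4 flower bud arrays (left) and the 4 root arrays (right), over members well above background on all 4 arrays of that tissue. Late pollen genes span 0.90 to -0.86 over the flower bud arrays and low oxygen genes 0.72 to -1.12 over the root arrays, while the reference genes stay between -0.07 and 0.03.

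Seed maturation genes had 3 of 7 members higher in flower buds, and the list did not pass (mean 0.69, camera adjusted p = 0.675, adjusted p = 0.733 with an estimated correlation). The regulator FUS3 differed by 3.21 ± 0.14, well above background on 2 of 4 root arrays, and the storage albumin SESA4 was at least 3.51-fold higher in flower buds. Under normexp the list had a mean of -0.21 and SESA4 was not called, at 0.38. CRU3, OLEO2, LEC1 and ABI3 were not called, at -0.82, 0.26, -0.39 and -0.89.

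Actin genes named for reproductive tissues did not move together: ACT1, ACT12 and ACT4 were higher in flower buds by 1.58 ± 0.11, 4.92 ± 1.16 and 2.60 ± 0.39, ACT11 was higher in roots at -1.49 ± 0.14, and ACT3 was not called at 0.76 ± 0.11. The list did not pass (mean 1.67, camera adjusted p = 0.296, adjusted p = 0.583 with an estimated correlation). ACT12 and ACT4 were well above background on 1 and 2 of 4 root arrays, and the difference of ACT12 was 4.27 without root replicate 1 and 6.13 without root replicate 3. With scaling on the reference genes ACT3 was called, at 1.07.

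Among 10 reference genes, chosen as transcripts commonly used to normalise PCR measurements, ACT8 and UBC9 were higher in roots at -2.28 ± 0.10 and -1.29 ± 0.08 and 8 were not called. YLS8, FBOX, UBC21, ACT7, PP2AA3 and TIP41L lay at -0.92 ± 0.10, -0.63 ± 0.11, -0.61 ± 0.08, -0.50 ± 0.10, -0.43 ± 0.09 and -0.38 ± 0.08, and SAND and RHIP1 at 0.10 ± 0.09 and 0.10 ± 0.08. SAND and RHIP1 turned to -0.06 and -0.06 with centring on the array median, where YLS8 was called at -1.07. The differences of the list lay below those of other genes, towards roots (mean -0.68, camera adjusted p = 0.0197, adjusted p = 0.120 with an estimated correlation). With scaling on these genes themselves, UBC9 was under 2-fold at -0.98 and the camera adjusted p was 0.0664.

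By the software's flag for signal well above background, more genes were measured in flower buds than in roots. Of 25383 genes with a probe, 21211 were well above background on all 4 flower bud arrays, 19055 on all 4 root arrays and 18003 on all 8 arrays. Genes above background on all arrays of flower buds and on none of roots numbered 1640, against 646 for the reverse, a ratio of 2.54. With 1 common limit on the scaled signal of all arrays the totals were 20302 and 19687, and the genes in 1 tissue alone 1378 and 1026, a ratio of 1.34. By the software's flag for positive and significant signal the genes in 1 tissue alone were 799 and 253. The share of genes above background per array was 82.1%, 76.4%, 76.8% and 80.7% on root replicates 1 to 4 and 87.6%, 86.8%, 86.4% and 85.1% on flower bud replicates 1 to 4. The scanner software put the spot-to-spot variation of root replicates 2 and 3 out of its range, with a median coefficient of variation of 9.34% and 10.9% against 4.66% to 7.26% on the other arrays.

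Replicates of both tissues were close to each other. The median SD per gene over 4 arrays was 0.17 on the log2 scale in flower buds and 0.21 in roots. Each array's median absolute deviation from its tissue mean averaged 0.116 ± 0.0227 (SD, n = 4) in flower buds and 0.148 ± 0.0276 (SD, n = 4) in roots. The difference was not larger than chance in an exact two-sided permutation test over 70 ways of dividing the arrays (p = 0.143; smallest possible p = 0.0286).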

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

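The tests of late pollen and photosynthesis genes were chosen after the result was seen, while those of the number of calls and of genes measured in 1 tissue were written before.

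In 8 of 135 groups of 4 arrays, over named genes and 3 measures of whole arrays, 1 array stood far from the other 3; chance alone gives about 1 in every 20, or 6.75. For RBCS2B the log2 signal relative to the array's 75th percentile was 6.56 on flower bud replicate 4, against 6.65 to 6.66 on the others. AT2G10940 was at -6.41 on root replicate 4, against -5.35 to -5.15. MCM6 lay at -2.44 on root replicate 1, against -3.16 to -3.07. ACT3 was at 2.77 on root replicate 4, against 3.04 to 3.06, and PP2AA3 at 1.56 on root replicate 3, against 1.31 to 1.34. ACT8 was at 5.06 on root replicate 1, against 5.27 to 5.28. ACT7 was at 3.94 on flower bud replicate 4, against 4.12 to 4.15, and FBOX at -0.74 on root replicate 2, against -0.37 to -0.31.

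Probes that matched no locus also carried signal: of 5443 tested, 1416 were higher in flower buds and 1220 higher in roots, and their genes were not analysed here.

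The 12220 genes called were set against other groupings of the arrays. Of the 35 ways to divide the 8 arrays into 4 and 4, 1 gave as many, the real one, and the highest of the others gave 0 calls in limma. At an unadjusted p under 0.05 the real division gave 18485 genes and the highest of the others 861. Every other division mixes roots with buds, which puts the tissue difference into the spread within its groups and keeps calls few. The others therefore give no reference without a difference, and the comparison does not exclude chance beyond 1 division in 35.

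More genes were measured in flower buds alone (1640) than in roots alone (646). Without the noisier root arrays 2 and 3 the counts were 1728 and 772, a ratio of 2.238, so an excess remained. Whether those arrays add to the excess is not decided by this, because leaving them out eases the rule for both counts. Fewer root arrays must then lack signal for flower buds alone, and fewer must show it for roots alone. The flower bud arrays were all kept, so the rule was no longer the same for both tissues. A different background level on each array stays open: with 1 common limit on the scaled signal the counts were 1378 and 1026, a ratio of 1.343, which lies between the bounds set beforehand. Tissue itself is the biological explanation that the design names, and it was not tested apart from the row on the slide, which cannot be told apart from tissue.

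Late pollen genes differed between the 4 flower bud arrays, with a range of 1.754 in their median deviation over the 20 genes tested. Noise or scaling of whole arrays is argued against, since the highest of 10000 random lists matched on expression had a range of 0.716. Noise of dim spots is argued against as well: over the 5 members above the 75th percentile of the array in flower buds the range was 1.883, against 0.994 for the highest random list. A first filter, on members well above background, removed none of the 20 and tested nothing. The random lists hold unrelated genes, so that a wider range shows that the members moved together but not why. The deviations of 0.90, 0.27, -0.19 and -0.86 fell in the order of the replicate numbers. That is also the order of the columns on the slide, so an effect of position was not tested apart. The order was not particular to late pollen genes. On the flower bud arrays the floral terpene, aliphatic glucosinolate, touch and wound and floral organ identity lists, among others, fell in the same order. The anther and tapetum list and the reference genes, among others, did not. The labels give no bud stage, so no biological explanation was tested, and pools that differ in the stage of their buds may be 1 hypothesis that stays open.

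Of 46 list ranges between the replicates of a tissue, 7 on the flower bud arrays and 4 on the root arrays were above all 10000 random lists, late pollen among them. The widest others were 2.53 for floral terpenes and 1.34 for aliphatic glucosinolates on the flower bud arrays, and 1.84 for low oxygen and 1.47 for touch and wound genes on the root arrays. The causes were not tested.

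Photosynthesis genes were above background in roots, 25 of 30 on all 8 arrays. Bud tissue or its RNA in the root samples would give each gene the same difference, but the SD over those 25 genes was 2.124, against a median SE of 0.185, so that this cannot be the whole source. The differences ran from 1.96 for PRK to 10.42 for GAPA, genes named after their values were seen. Binding of other transcripts of the same family to the probe stays open, because probe sequences for 0 of the 30 genes were used here. Expression in the roots themselves is a biological explanation that stays untested.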

How the results depend on the processing

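Omitting root replicates 2 and 3 and raising values to the highest floor were chosen after seeing the data. The 88 named genes kept direction and side of the threshold in 2039 cases. The call was lost in 15 cases and gained in 9, mostly under other thresholds. The direction turned in 2, SAND to -0.058 and RHIP1 to -0.060 when arrays were centred on the median. These counts are a weak check, since most named genes were picked for large differences. Other thresholds, filters, eBayes settings, separate probes and the replicate block cannot change the fitted difference of a named gene. Requiring signal on all 8 arrays left 41 of the 88 tested, and the others were not counted there. Settings other than thresholds, filters and separate probes gave 10805 calls (normexp, 10682 of them among the 12220 reported) to 12683 (reference genes, 11359 shared). The cause of the following moves lies in the construction of the alternative. Requiring signal on all 8 arrays left 4008 genes higher in flower buds against 4452 in roots. Testing every probe gave 19038 calls, 10363 higher in flower buds and 8675 in roots. No minimum fold gave 18290 calls, 9918 higher in flower buds and 8372 in roots. An adjusted p under 0.01 with 4-fold gave 7466 calls, 4099 and 3367 by direction. The median difference of all genes was 0.14 as reported, 0.46 with scaling on the reference genes, 0.03 with normexp and -0.01 with median centring.

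Normexp turned the mean of the seed maturation list to -0.211; the cause was not tested. It moved 57 of the 88 named differences by over 1.5-fold, against 24 with raised floors, 14 with the mean of all probes, 12 without root replicates 2 and 3 and 7 with quantile normalization. With an estimated correlation 0 lists passed camera, 10 of 26 at an unadjusted p under 0.05, and fry passed 25. Lists that passed fry but not camera at the preset correlation were aliphatic glucosinolates, seed maturation and reproductive actins. Their fry adjusted p-values were 0.00229, 0.000243 and 0.000967. The positive-and-significant flag left 799 genes in flower buds alone and 253 in roots alone; the cause was not tested.

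Leaving out each array in turn gave 12078 to 12395 calls, 6587 to 6906 higher in flower buds and 5473 to 5553 higher in roots, with 22 to 23 lists, 21211 to 21566 and 19055 to 19287 genes detected, and 1652 to 1972 and 646 to 714 in 1 tissue alone. The difference in spread ranged from -0.0489 to 0.00158, the last without root replicate 4. Same-numbered arrays did not deviate together (r over genes -0.27, 0.05, -0.01 and 0.10), and r for arrays of unlike number was -0.17 to 0.21. These values gave no sign of pairing by number, but they cannot exclude that same-numbered samples came from the same plants. The replicate block gave 12178 calls, 6673 and 5505, of which 12152 were shared. Dim signal over background limits folds, which are given as bounds only where no array of a tissue was well above background. Genes well above background on some arrays of a tissue are given as fitted differences. Those rest in part on signal not well above background and are not measured folds.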

Other observations

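Gene families were grouped by the letters of their symbols after seeing the data, and the genes named in them were chosen after their values were seen. The test of neighbouring genes was planned before its result was seen. Its random range for pairs with different leading letters in their symbols was added afterwards. For 123 families with at least 12 tested members, the share called in each direction was set against all 9540 tested genes with a symbol by a one-sided Fisher's exact test, in 246 tests with Benjamini-Hochberg adjustment; 13 families passed towards flower buds and 19 towards roots. Members of a family are not independent of each other. Shared letters do not show that genes are related by sequence, which was not examined. A family could pass with members in both directions. CYP genes passed towards roots with 84 of 192 higher in roots and 68 higher in flower buds, and MYB genes with 40 and 34 of 100. With scaling on the reference genes these counts were 79 and 72 for CYP and 36 and 35 for MYB.

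Several families had more members higher in flower buds. Of 34 genes with LCR symbols 25 were higher there and 1 in roots (adjusted p = 2.74e-05), and LCR17 and LCR5 were at least 333-fold and 235-fold higher. Of 16 SCRL genes 11 were higher in flower buds and 1, SCRL7 at -4.55 ± 0.14, in roots (adjusted p = 0.0224). RALFL peptide genes were higher in flower buds for 15 of 20 members (adjusted p = 0.00154), RALFL8 at least 1114-fold, while RALFL27 was at least 411-fold higher in roots. Fatty acid elongases of the KCS family were higher in flower buds for 17 of 21 members (adjusted p = 0.000175), with KCS15 at least 383-fold higher, and SAUR genes, which respond to auxin, for 11 of 14 (adjusted p = 0.00598). CHX cation exchangers were higher in flower buds for 11 of 16 (adjusted p = 0.0224). Under normexp the counts towards flower buds were 17 for LCR, 10 for SCRL, 10 for RALFL, 16 for KCS, 9 for SAUR and 7 for CHX, and no family turned direction.

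Other families had more members higher in roots. WRKY transcription factor genes were higher in roots for 37 of 62 members and higher in flower buds for 10 (adjusted p = 6.91e-07), with WRKY65 at -10.49 ± 0.24 and WRKY12 at 7.10 ± 0.22. CIPK protein kinase genes were higher in roots for 17 of 21 (adjusted p = 8.33e-06), although CIPK9 was higher in flower buds by 4.96 ± 0.16. Glutathione transferases of the GSTU and GSTF classes were higher in roots for 16 of 23 and 9 of 12 members (adjusted p = 0.000270 and 0.00598), and laccases for 10 of 13 (adjusted p = 0.00238). These directions held with quantile normalization, median centring, normexp and scaling on the reference genes, the last giving 35, 14, 16, 9 and 10 members higher in roots.

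Neighbouring genes shared direction more often than random arrangements gave. Of 5811 pairs of neighbouring genes that were both called, 57.94% were called in the same direction, against a mean of 50.5% and a highest value of 52.5% over 1000 random arrangements of the calls within chromosomes. Among 1016 such pairs whose symbols have different leading letters the share was 54.1%. Random arrangements gave a mean of 50.5% and a highest value of 55.6% for these pairs, and 7 of the 1000 were as high. Related genes with unlike symbols can remain among these pairs. The longest runs, of 10 genes each, were both higher in roots; 1 of them holds PEN1, BARS1 and BIA1, and the other PRA1.B3, LAC12, DREB2A and PYL5. The 57.94% excludes a chance arrangement of the calls but not any of its causes: common regulation and transcripts of duplicated genes that bind each other's probes may both add to it, and neither was tested apart.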
